A study of Mus musculus with 2 samples.

How the data were processed

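Crypt cells of the ileum of Atoh1CreER-T2;R26RTom mice were released with EDTA, dissociated with TrypLE, sorted by flow cytometry as live Tom+ cells and made into 10x Genomics 3′ libraries, per the labels' protocols. Reads were aligned to mm10 and UMIs counted with Cell Ranger 3.0.2 and STAR, per the submitters' processing notes. The deposited matrices hold raw UMI counts per gene and barcode with no cell filter, and the first line of each names Cell Ranger 3.0.2, per the file headers. They cover 31053 genes in 2 libraries. A deposited table lists the cells the authors kept, with a class name per cell, the number of UMI counts and genes per cell, and the percent of mitochondrial UMIs. The percent values are mitochondrial UMIs of all UMIs of a cell, per the file headers, and how the authors set the limits and assigned the classes is not given in the sources used here. By the values of this table, listed cells had more than 600 and fewer than 3000 genes and under 7% mitochondrial UMIs. By the matrix, 5304 of the 5305 listed cells of replicate 1 and all 6257 of replicate 2 lay within these limits. The table's UMI total equalled the matrix total in 77.6% of cells of replicate 1 and 73.9% of replicate 2, and differed by at most 11 and 25 UMIs in the rest. The table's library names were matched to the replicates by the names of the matrices and checked with these totals.

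The matrices held 66021021 UMIs in replicate 1 and 40869800 in replicate 2, of which 32656481 and 27014983 lay in listed cells. Depth sets what can be seen in a single cell: 1276 of the 11562 cells had fewer than 2000 UMIs, and genes of a few CPM give a UMI in only a small share of cells. Exact (Clopper-Pearson) 95% binomial intervals are given for shares of cells, and 3 counts were taken as the limit that a count of 0 allows. Both cover counting error only.

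The comparisons, tests, named-gene rule, lists and first set of alternatives were chosen before the data were examined, except where stated below. Since there was 1 group, no test between groups of samples was made. Raw counts of each of the 12 classes, all of which had at least 20 cells per library, were added up within each library, which gave 24 sums. They were analysed in R 4.3.3 with edgeR 4.0.16. The function filterByExpr kept 10994 genes. A quasi-likelihood model with robust dispersion was fitted with class and library as terms. It had 11 residual degrees of freedom and a median biological coefficient of variation of 0.0641. A prior count of 2 was used only for the log2 levels of single sums. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The library term was kept because differences between libraries were shared among classes: over 66 pairs of classes the median correlation of these differences across 3827 genes was 0.297 (0.0551 to 0.776), genes not being independent replicates. Fixed cell type markers were left out of all counts of called genes, which left 10910. The contrasts were SEC-PRO against ISC, PANETH and GOBLET, PANETH against GOBLET, and each class against the equally weighted mean of the others.

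TMM factors were computed from genes with an average log2 CPM of at least 6. The plan named TMM without a choice of genes. This choice was made after first calls had been seen, on simulated data, by trying TMM over all genes, TMM with singleton pairing, relative log expression and TMM over abundant genes. In the self-test, TMM over all genes shifted contrasts with the shallow GOBLET sums by -0.185 and -0.181 on the log2 scale, against 0.0303 and 0.0125 with the more abundant genes. Levels are CPM with these factors. Of the 30 gene lists fixed in advance, 25 had enough measured genes for the set test, camera of limma 3.58.1 on voom values. It was 2-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists within a contrast. It ran on the 3827 genes with an average log2 CPM of at least 5. That minimum was also chosen on simulated data after first calls had been seen, since camera over all genes called unchanged lists in contrasts with GOBLET, and minimums of 4 and 6 and camera on counts were tried too. The same test was run with an estimated correlation. A list's counts come from the edgeR test, over all genes and adjusted over the list alone, and genes that mark a compared class were left out of the lists.

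Genes were named by a fixed rule. For each of the 4 pairwise comparisons these were the 8 largest and 8 smallest log2 changes among genes with an adjusted p under 0.05, an average log2 CPM of at least 5 and the same direction in both libraries, leaving out markers, mitochondrial, ribosomal protein and haemoglobin genes and unnamed models. To them were added the 3 members with the smallest p of each list that passed camera, the 5 largest increases of each class against the others, and, always, Atoh1, Lgr5, Olfm4, Apc, Ctnnb1, Cd44 and Sox9. Gene IDs and coordinates are from GENCODE M21 on mm10. A fold against a class with no counts was computed against a floor of 3 counts over both of its sums. For shares of cells with a transcript, each cell was thinned to 2000 UMIs, which kept 10286 cells. The free RNA of the droplets was read from barcodes with at most 50 UMIs, 821694 in replicate 1 (1208373 UMIs) and 577200 in replicate 2 (1166363 UMIs), and its share of a sum was bounded from above with Paneth and goblet transcripts, at between 2.63% and 24.8%.

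The edgeR step was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. It recovered 50% and 84% of them for SEC-PRO against GOBLET (10816 genes), 94% and 100% for SEC-PRO against PANETH (10753 genes), 100% and 99% for SEC-PRO against ISC (10770 genes) and 25% and 87% for PANETH against GOBLET (10777 genes). False calls were 1.47%, 1.52%, 0% and 2.61% of calls. On 3827 simulated genes camera called the raised list in all 4 comparisons, and falsely called 1 other list in each of the pair of comparisons with GOBLET. Since both minimums were chosen on data simulated in the same way, these rates are not an independent check. Recovery of changes in genes at lower levels was not measured.

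The settings varied as planned were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, no library term, either library left out, cells with at least 2000 UMIs and at most 10% mitochondrial UMIs, Scrublet doublets removed, thinned cells, count splitting, free RNA subtracted, lists with an estimated correlation or with markers kept in, own clustering, unthinned shares and shares with at least 2 UMIs. Scrublet's own threshold called 4 cells (0.0346%), so the 5% of cells with the highest scores, 578, were removed as an alternative added after seeing the data. Also added then were GOBLET-PRE in place of GOBLET, no factors (library size alone), TMM over all genes, and unlisted barcodes added back and placed by correlation with class means over 2142 genes. Scrublet was run in scanpy 1.11.5. Own clustering used leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8), which gave 19 clusters, and 17 on the split counts. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used for the rest. Barcodes outside the authors' table were left out of the comparisons between classes.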

Results

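Single-cell RNA-seq was carried out on cells of the mouse ileal crypt that carried a red fluorescent label (Tom+). The mice combined Atoh1CreER-T2, a recombinase that is made where Atoh1 is active and enters the nucleus after tamoxifen, with R26RTom, a reporter that keeps a cell and its progeny red after recombination. Atoh1 encodes the transcription factor that commits crypt cells to secretory fates. Tamoxifen was given in 2 doses of 1 mg/mL, 24 h apart, and live Tom+ cells were sorted 12 h later. The sources name 1 group with 2 libraries, replicate 1 and replicate 2, so the data held no comparison between groups of animals. The comparisons were therefore made between the 12 cell classes that the authors assigned within each library, and they address which cell states a recent Atoh1-driven label marks and how these states differ.

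Replicate 1 held 5305 listed cells with 32656481 unique molecular identifiers (UMIs), and replicate 2 held 6257 listed cells with 27014983 UMIs. The median cell had 5706 UMIs and 1999 genes in replicate 1 and 3503 UMIs and 1464 genes in replicate 2. Listed cells held 49.5% of all UMIs of replicate 1 and 66.1% of those of replicate 2. UMIs of a class were added up within each library, which gave 24 sums of between 129631 UMIs (EC, replicate 1) and 13770059 UMIs (GOBLET-PRE, replicate 1). Levels are given as CPM, counts normalised to the depth of a sum and scaled by TMM factors, as the mean and SD of the 2 libraries, and changes as log2 values with their SE. All levels are thus from n = 2, and the labels do not say whether the libraries came from separate animals. The library term of the model removed differences between the libraries that were shared among classes. The p-values therefore measure only the spread, counting error included, that was left between these libraries within classes. They do not cover the shared differences between the libraries. Because the classes were defined from the same expression values, p-values of genes that set the classes apart are not independent evidence.

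The sorted cells were mostly secretory, from proliferating progenitors to mature goblet and Paneth cells. GOBLET-PRE, read here as precursors of the mucus-making goblet cells, made up 33.6% ± 14.3 (SD) of listed cells, with 43.7% in replicate 1 (95% exact binomial interval 42.4 to 45.0%) and 23.4% in replicate 2 (22.4 to 24.5%). ISC, the intestinal stem cells, made up 10.4% in replicate 1 (9.61 to 11.3%) and 27.8% in replicate 2 (26.7 to 28.9%), a mean of 19.1% ± 12.3. SEC-PRO, the secretory progenitors, held 14.7% and 13.5% of cells, and GP, whose name is not spelled out in the sources used here, held 12.9% and 13.2%. Mature GOBLET cells were rare, at 0.792% and 1.34%, or 42 and 84 cells. Paneth cells, which secrete antimicrobial peptides at the crypt base, were split into PANETH-PRE (4.66% ± 0.559) and PANETH (5.19% ± 1.52). The hormone-making cells of the 3 classes EEC-PRE, EC and NON-EC came to 4.05% ± 0.336, tuft cells (TUFT) to 2.66% ± 0.530 and ENTERO-PRO, read as enterocyte progenitors, to 2.54% ± 0.450. All classes other than ISC and ENTERO-PRO together held 87.4% of cells in replicate 1 and 69.3% in replicate 2. The intervals cover counting error only, and the libraries differed by far more than that in ISC and GOBLET-PRE. The ISC share of replicate 2 was 2.67 times that of replicate 1. It was 1.53 times as high (1.45 to 1.61) when unlisted barcodes with 3000 or more genes or at least 7% mitochondrial UMIs were returned and placed in the class with the nearest mean profile. In clusters computed anew and named by fixed markers, secretory progenitor clusters held 12.6% of cells. SEC-PRO, the largest class in each of these clusters, held 14.1% of listed cells. Goblet clusters held 47.3%, against 34.6% for GOBLET-PRE and GOBLET together. GP was the largest class in none of the clusters, so the split of progenitors and goblet cells was not reproduced.

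**Figure D1:**
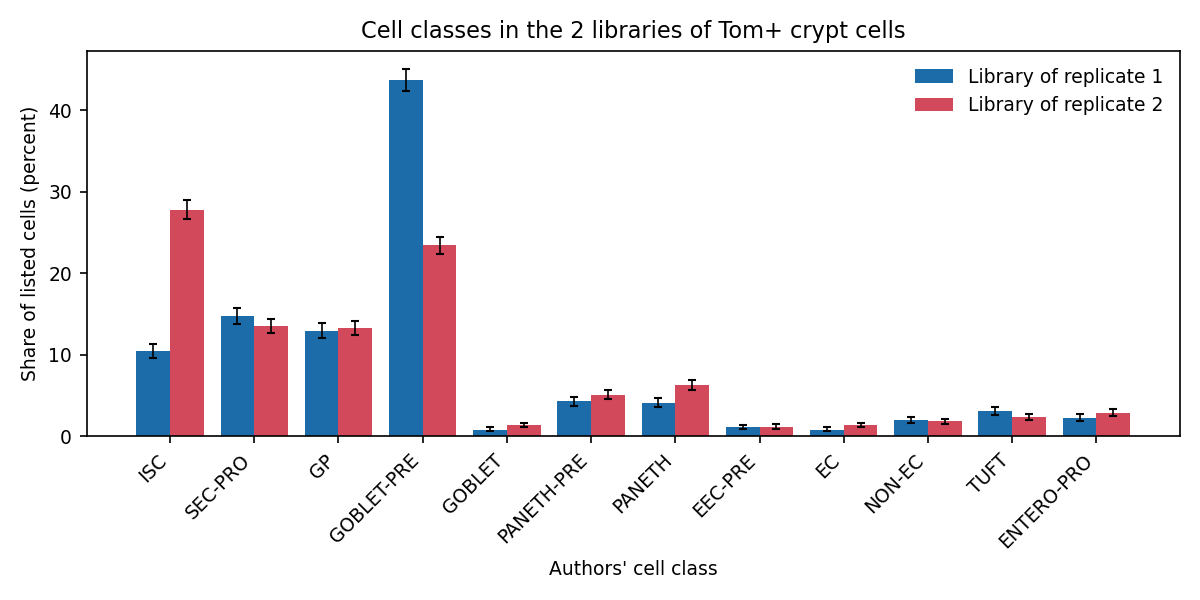
Bars show the percent of listed cells in each of the 12 classes (vertical axis, percent), blue for replicate 1 and red for replicate 2, with 95% exact binomial intervals. GOBLET-PRE (43.7% and 23.4%) and ISC (10.4% and 27.8%) differed most between the libraries in percentage points, while SEC-PRO (14.7% and 13.5%) and GP (12.9% and 13.2%) lay close together.

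Lgr5, the receptor that marks crypt base stem cells (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780, minus strand), gave a UMI in 13.2% (10.4 to 16.4%) and 9.77% (8.34 to 11.4%) of ISC once each cell was thinned to 2000 UMIs. In GOBLET-PRE, which should lack the gene, the thinned shares were 0.177% and 0.155%. Without thinning they were 24.2% and 14.3% in ISC, at median depths of 5825 and 3973 UMIs, and 0.604% and 0.410% in GOBLET-PRE, at 6104 and 3369 UMIs. PANETH-PRE reached 8.85% (5.49 to 13.3%) and 11.3% (7.98 to 15.5%), at a median of 6600 and 4342.5 UMIs (24.3% and 20.6% without thinning). Its Lgr5 level was 54.5 ± 4.56 CPM, beside 47.8 ± 16.2 CPM in ISC and 58.2 ± 27.5 CPM in PANETH. In unscaled CPM it was 43.4 and 50.2 beside 19.9 and 19.7 in the free RNA of barcodes with at most 50 UMIs. PANETH lay below this free RNA when unscaled, with 85 and 51 counts in 4782527 and 5155992 UMIs. Free RNA made up at most 2.63% and 7.43% of UMIs in the PANETH sums, so it could bring only a small part of these counts. Meanwhile Olfm4, another stem cell transcript, was at 160 and 164 unscaled CPM in PANETH-PRE against 2254 and 1085 in ISC. Olfm4 (ENSMUSG00000022026, chromosome 14, 79984081 to 80023139, plus strand) was seen in 67.4% and 58.4% of thinned ISC and in 3.33% and 3.88% of thinned GOBLET-PRE, or 77.0% and 66.5% against 9.88% and 6.55% without thinning. Cells with under 2000 UMIs, 375 in replicate 1 and 901 in replicate 2, were left out of the thinned values.

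Atoh1 (ENSMUSG00000073043, chromosome 6, 64729125 to 64731245, plus strand) gave a UMI in 22.3% (19.2 to 25.7%) and 19.4% (16.5 to 22.5%) of thinned SEC-PRO, at median depths of 5413 and 3488.5 UMIs, and in 2.72% and 4.63% of thinned ISC. The unthinned shares were 44.6% and 32.3% in SEC-PRO and 7.96% and 9.60% in ISC. Dll1, a Notch ligand of secretory progenitors, was seen in 17.7% and 14.5% of thinned SEC-PRO and 2.14% and 3.92% of thinned ISC (37.5% and 26.8% against 8.50% and 8.40% without thinning). Transcripts of the proliferation marker Mki67 were found in 63.8% and 58.8% of thinned SEC-PRO, 40.4% and 43.2% of ISC, 10.8% and 9.74% of GP, and 2.76% and 3.36% of PANETH. These no longer divide and had median depths of 23375 and 12874 UMIs. Without thinning, Mki67 was seen in 79.2% and 65.8% of SEC-PRO and 12.8% and 12.2% of PANETH. Neurog3, the transcription factor that starts the enteroendocrine programme, was seen in 79.6% and 78.3% of thinned EEC-PRE (89.5% and 76.7% without thinning, at 3897 and 2157 UMIs). It was seen in 0 of 130 and 0 of 87 thinned TUFT cells, which allows up to 2.31% and 3.45% of cells with a captured UMI at this depth and says nothing of lower levels. TUFT cells also gave 0 without thinning, at median depths of 3403 and 2317 UMIs. Apc, the tumour suppressor that restrains Wnt signalling (ENSMUSG00000005871, chromosome 18, 34220924 to 34322552, plus strand), was seen in 18.3% and 16.5% of thinned SEC-PRO and 13.8% and 14.1% of thinned ISC (39.1% and 27.4% against 33.3% and 27.4% without thinning). No class is known to lack it.

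**Figure D2:**
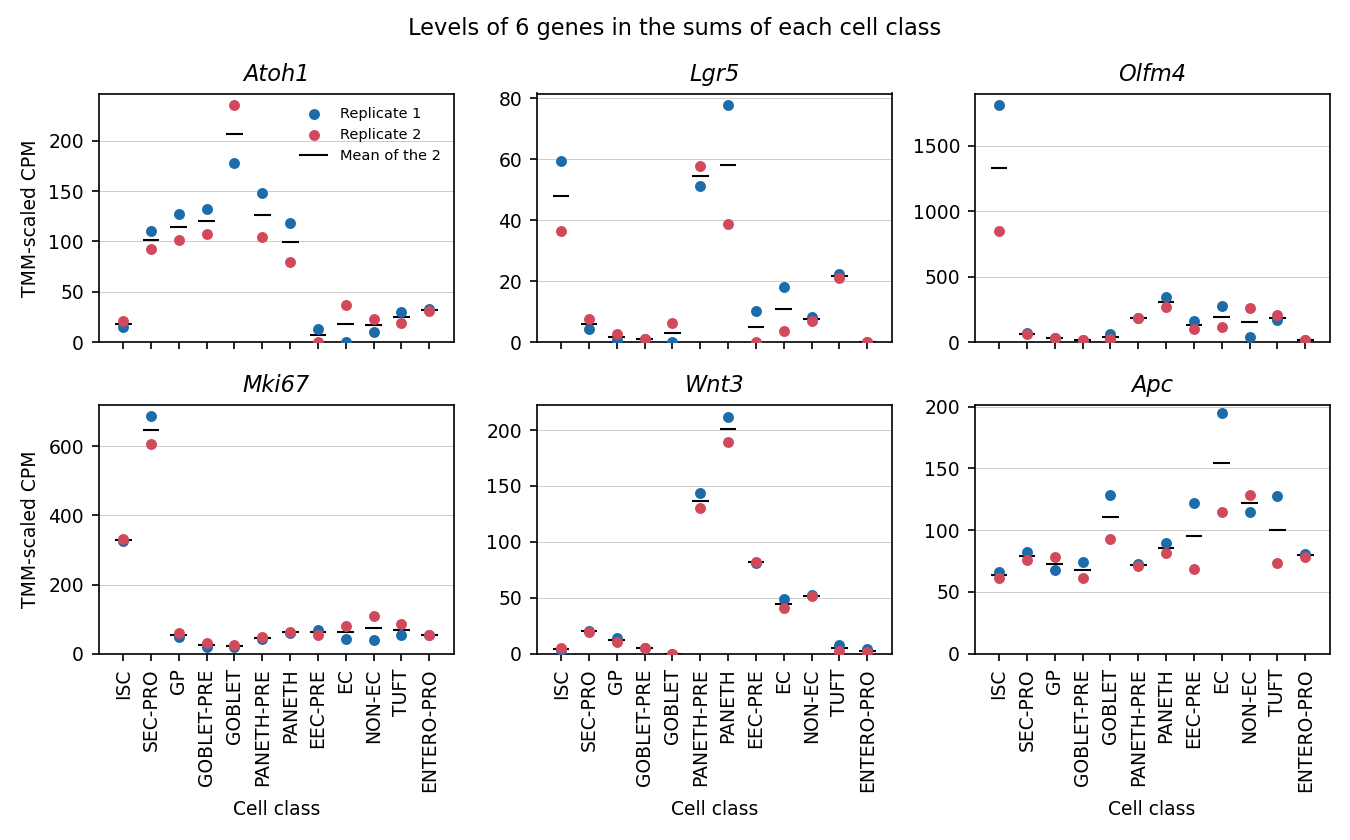
Each panel shows the TMM-scaled CPM of 1 gene in the 12 classes, with a dot per library and a line at the mean of the 2 libraries. Atoh1 averaged 101 CPM in SEC-PRO and 18.1 in ISC, Lgr5 47.8 in ISC, 54.5 in PANETH-PRE and 58.2 in PANETH, Mki67 647 in SEC-PRO, and Wnt3 201 in PANETH.

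Secretory progenitors were compared with stem cells to see what accompanied entry into the secretory lineage. SEC-PRO had 5.20-fold more Atoh1 than ISC (101 ± 13.0 against 18.1 ± 3.63 CPM, log2 2.38 ± 0.19, edgeR adjusted p = 4.62e-10). Lgr5 was 7.94-fold lower (6.07 ± 2.27 against 47.8 ± 16.2 CPM, log2 -2.99 ± 0.27, edgeR adjusted p = 9.99e-10) and Olfm4 fell from 1329 ± 681 to 64.1 ± 4.96 CPM (log2 -4.33 ± 0.41, edgeR adjusted p = 3.90e-06). The 8 largest increases included Creb3l1, a membrane-bound transcription factor of secretory cells (ENSMUSG00000027230, chromosome 2, 91982328 to 92024502, minus strand), at 265 ± 15.9 against 49.5 ± 23.2 CPM (5.17-fold, edgeR adjusted p = 5.69e-18). Another was Ern2, an endoplasmic reticulum stress sensor of mucus-making epithelia (155 ± 4.89 against 30.2 ± 14.6 CPM, log2 2.29 ± 0.15). Kit, a receptor tyrosine kinase (197 ± 60.1 against 39.5 ± 21.3 CPM, log2 2.28 ± 0.12), the chaperone gene Dnajc10 (log2 2.30 ± 0.15), the chemokine gene Ccl9 (2.56 ± 0.27), Guca2b, which encodes uroguanylin (2.30 ± 0.29), Selenom (2.25 ± 0.20) and Plcb1 (2.31 ± 0.19) completed them. The 8 largest decreases included Otc, the urea cycle enzyme ornithine transcarbamylase (9.48 ± 1.07 against 152 ± 15.03 CPM, log2 -3.99 ± 0.23), and Dmbt1, a secreted glycoprotein (53.2 ± 26.8 against 473 ± 105 CPM, log2 -3.23 ± 0.31). Others were the chemokine gene Ccl25 (log2 -2.68 ± 0.23), Nlrp6 (-3.37 ± 0.24), Mgst1 (-3.56 ± 0.29), Tm4sf20 (-3.57 ± 0.22) and Prap1 (-2.84 ± 0.37), which overlaps Fuom on the opposite strand. Kcnq1ot1, a long noncoding RNA antisense to Kcnq1 (ENSMUSG00000101609, chromosome 7, 143203458 to 143296549, minus strand), was lowest of all (6.68 ± 0.680 against 154 ± 18.5 CPM, log2 -4.53 ± 0.18). Since the sources used here do not give the strand setting of the counting, its level and that of Prap1 are uncertain. Of the genes fixed in advance, Cd44, a Wnt-responsive adhesion receptor, fell by 0.97 ± 0.16 on the log2 scale (20.3 against 39.9 CPM). Ctnnb1, which encodes beta-catenin, and Sox9 did not pass (log2 -0.01 ± 0.10 and 0.04 ± 0.12, edgeR adjusted p = 0.982 and 0.860). Apc was 78.7 ± 4.61 against 63.6 ± 3.96 CPM (log2 0.30 ± 0.12, edgeR adjusted p = 0.0427), and this call was lost under 8 alternatives, among them DESeq2 size factors (0.17), TMM over all genes (0.20) and no replicate block (0.31).

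The secretory machinery rose together in SEC-PRO relative to ISC. Members that went against their list, or that are named because 5 or fewer of a list passed, were chosen after their values were seen, here and in the comparisons that follow. Of 30 measured genes of protein translocation and endoplasmic reticulum (ER) to Golgi transport, 29 rose and 0 fell (29 and 0 when adjusted over the list alone; median log2 0.97, camera adjusted p = 4.01e-11). Among them were Kdelr2 (log2 1.37), Sec11c (1.18) and Sec24d (1.90). Of 24 ER stress and unfolded protein response genes, 23 rose (24 over the list alone; median 1.12, camera adjusted p = 5.64e-11). Calr, the chaperone calreticulin, stood at 1141 ± 26.0 against 503 ± 75.3 CPM and Sdf2l1 and Manf at log2 1.49 and 1.18. Mucin glycosylation genes followed, with 14 of 18 up and 1 down, Gcnt4 (log2 -3.56 ± 0.78; 15 and 1 over the list alone; median 1.55, camera adjusted p = 1.47e-07). Among them were C1galt1 (283 ± 38.9 against 89.4 ± 8.68 CPM), Galnt12 (1.83) and Galnt7 (1.73). Of 12 secretory transcription factors 9 rose (9 over the list alone; median 1.42, camera adjusted p = 2.17e-05). Among them were Creb3l1, named above, Spdef, a goblet and Paneth maturation factor (135 against 28.8 CPM, log2 2.16 ± 0.13), and Foxa3 (1.47). With an estimated correlation the adjusted p was 0.19 for each of these 4 lists. Of 30 G2/M genes 27 rose (29 over the list alone; median 0.56, camera adjusted p = 8.73e-04, adjusted p = 0.305 with an estimated correlation). Among them were Cenpe (181 ± 31.6 against 84.0 ± 0.660 CPM), Kif20b (0.78) and Tacc3 (0.81). Mki67 was at log2 0.99 ± 0.14. G1/S genes were split, 5 up (Rrm2, Cdc6, Ccne2, Clspn and Fen1) and 4 down (Cdt1, Rfc2, Chaf1b and Dut) of 30 (camera adjusted p = 0.147). Cell cycle inhibitors also rose, 8 of 16 (9 over the list alone; median 0.40, camera adjusted p = 0.0433, adjusted p = 0.261 with an estimated correlation), with Cdkn2d (1.77), Gadd45b (1.44) and Btg2 (1.25). Fetal-like and injury-response genes rose in 8 of 11 cases (9 over the list alone; median 1.09, camera adjusted p = 0.00223, adjusted p = 0.205 with an estimated correlation), with Krt7 (1.15), Anxa5 (1.40) and Cyr61 (1.09). Dissociation and stress response genes, which include immediate-early and heat-shock genes, rose in 14 of 16 cases (14 over the list alone; median 1.12, camera adjusted p = 1.44e-04, adjusted p = 0.261 with an estimated correlation), with Zfp36 (1.11), Ier2 (0.67) and Dusp1 (1.12).

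Growth and antigen presentation genes fell in SEC-PRO relative to ISC. Of 30 cytosolic ribosomal protein genes 27 fell (29 over the list alone; median log2 -0.38, camera adjusted p = 1.38e-14), with Rpl22 at 955 ± 12.8 against 1293 ± 66.9 CPM and Rpl3 and Rpl10a at -0.43 and -0.40. Ribosome biogenesis genes fell in 20 of 30 cases (21 over the list alone; median -0.45, camera adjusted p = 8.06e-06), with the nucleolar genes Ncl (763 ± 117 against 1285 CPM), Nhp2 (-0.79) and Npm1 (-0.68). Oxidative phosphorylation genes fell in 25 of 30 (26 over the list alone; median -0.34, camera adjusted p = 1.28e-09). Among them were Uqcrc1 (-0.64) and Cox4i1 (-0.52). In the interferon response list 6 of 15 fell, with Ifitm2 (-0.94), Psmb9 (-1.05) and Psmb8 (-0.88) among them, and 2 rose, Irf7 (1.74 ± 0.23) and Gbp7 (0.75 ± 0.20) (7 and 2 over the list alone; median -0.34, camera adjusted p = 1.44e-04). With an estimated correlation the adjusted p was 0.19 for each of these 4 lists. Mitochondrial genome transcripts fell in 7 of 13 cases (9 over the list alone; median -0.31, camera adjusted p = 1.10e-04, adjusted p = 0.261 with an estimated correlation), with mt-Cytb (-0.53), mt-Nd1 (-0.49) and mt-Nd4l (-0.31). MHC class II genes, which present peptides to T cells, fell in 6 of 7 cases (6 over the list alone; median -1.16, camera adjusted p = 0.00580, adjusted p = 0.305 with an estimated correlation). Among them were H2-DMa (-1.48), the list's master regulator Ciita (-1.99) and H2-Eb1 (-1.50). Notch receptors and targets, too few for the set test, fell in 5 of 6 cases (median -2.003), namely Hes1 (-1.31 ± 0.12), Notch1 (-2.80 ± 0.26), Notch2, Nrarp and Dtx4, while Lfng, a modifier of Notch receptors, rose by 1.58 ± 0.27. Wnt target genes did not pass as a list, with 1 up (Prox1) and 5 down (Sp5, Myc, Ccnd1, Cd44 and Tnfrsf19) of 14 (camera adjusted p = 0.714). BMP signalling genes did not pass either (7 up and 2 down, Id1 and Id3, of 12, median 0.49 and mean 0.56 against a downward test, camera adjusted p = 0.714). Crypt niche ligands did not pass either (camera adjusted p = 0.0779), though 3 of 6 rose, Wnt3 (2.06 ± 0.22), Areg and Hbegf. Of 20 Wnt pathway components, Apc, Csnk1a1 and Tcf7l2 rose and Fzd5 fell (camera adjusted p = 0.472), and the list's median of 0.10 turned to -0.03 with DESeq2 size factors. In all, 2082 of 10910 genes rose and 1665 fell in this comparison, and 99.9% of them moved the same way in both libraries. Since calls were made from the same 2 libraries, this agreement is largely built in and is no check of the calls. Without the library term 1886 genes were called and 50.3% of the 3747 calls were kept, and in thinned cells 2413 were called and 61.2% kept. The share of calls that were increases was 55.6%, but 39.0% with DESeq2 size factors, 42.2% with TMM over all genes and 36.7% with count splitting, while DESeq2 size factors moved the median of all genes from 0.05 to -0.08.

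Secretory progenitors were next compared with mature Paneth cells, which mark the far end of 1 secretory branch. Cell division genes were the ones most raised in SEC-PRO: Ccnb2, a mitotic cyclin (ENSMUSG00000032218, chromosome 9, 70407692 to 70421547, minus strand), was 11.4-fold higher (89.1 ± 8.36 against 7.83 ± 0.735 CPM, log2 3.51 ± 0.30, edgeR adjusted p = 6.94e-13). Knl1 (log2 3.41 ± 0.27), Spc24 (3.38 ± 0.26), Kif20b (3.38 ± 0.24) and Cenpf (3.23 ± 0.18), which act at kinetochores and spindles, were among the 8. Nusap1 (3.27 ± 0.22) and the histone genes Hist1h1b (3.33 ± 0.35) and Hist1h2ap (3.26 ± 0.22) made up the rest of the 8. The 8 largest decreases were Clps, Pnliprp2 and defensin genes. Clps, the colipase (ENSMUSG00000024225, chromosome 17, 28558149 to 28560766, minus strand), was at 20055 ± 8737 CPM in PANETH and 55.9 ± 55.2 in SEC-PRO (log2 -8.78 ± 0.61, edgeR adjusted p = 1.61e-07). The log2 change was -9.62 in replicate 1 and -8.10 in replicate 2, and Clps in SEC-PRO (16.9 and 94.9 CPM) lay near its levels in ISC (22.1 and 77.4 CPM) and NON-EC (29.1 and 79.6 CPM). Subtracting free RNA reversed 0 of 278 values of named genes. How much of this Clps level free RNA made up is not given, so the fold is uncertain. So is that of the lipase gene Pnliprp2, at 6886 ± 2982 and 19.99 ± 19.5 CPM (log2 -8.61 ± 0.46). Defa29, Defa35, Defa23, Defa36, Defa5 and the defensin-like AY761184 lay between log2 -8.83 and -8.38, and counts of these near-identical copies are uncertain because reads can be shared among them. Free RNA in the droplets also carried defensin transcripts, with Defa24 at 48309 and 88902 CPM in barcodes of at most 50 UMIs. Lgr5 was 9.75-fold lower in SEC-PRO than in PANETH (6.07 ± 2.27 against 58.2 ± 27.5 CPM, log2 -3.28 ± 0.33, edgeR adjusted p = 6.14e-09). Without TMM factors its level in replicate 2 was nearly the same in both (30 counts in 3097584 UMIs and 51 in 5155992). Olfm4 (-2.26 ± 0.44), Sox9 (111 ± 2.21 against 271 ± 12.5 CPM, log2 -1.28 ± 0.13) and Ctnnb1 (-0.46 ± 0.12) were also lower. Cd44 was higher (1.53 ± 0.35), whereas Atoh1 (0.04 ± 0.20, edgeR adjusted p = 0.893) and Apc (-0.12 ± 0.15, edgeR adjusted p = 0.590) did not pass. The Cd44 call and the Ctnnb1 call were lost in thinned cells.

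By list, 30 of 30 G2/M genes were higher in SEC-PRO than in PANETH (30 over the list alone; median log2 3.03, camera adjusted p = 1.24e-08, adjusted p = 0.289 with an estimated correlation). Smc4 stood at 239 ± 6.25 against 32.9 ± 2.54 CPM and Cenpe at 181 ± 31.6 against 21.3 ± 2.20 CPM. So were 28 of 30 G1/S genes (28 over the list alone; median 1.91, camera adjusted p = 4.41e-04, adjusted p = 0.374 with an estimated correlation), with Rrm1 (2.26), Mcm4 (2.02) and Clspn (2.20). Ribosomal protein genes were higher in 19 of 30 cases (20 over the list alone; median 0.33, camera adjusted p = 1.04e-06, adjusted p = 0.424 with an estimated correlation), with Rpl14 (0.65), Rpl22 (0.58) and Rpl3 (0.55). Ribosome biogenesis genes were higher in 11 and lower in 3 of 30 cases, the 3 being Nop10, Polr1a and Ltv1 (12 and 5 over the list alone; median 0.27, camera adjusted p = 0.0198, adjusted p = 0.424 with an estimated correlation). Those higher included Npm1 (1.02), Ncl (0.85) and Nop58 (0.72). Oxidative phosphorylation genes were higher in 19 and lower in 2 of 30, the latter Ndufa1 (-0.68) and Uqcrq (21 and 2 over the list alone; median 0.34, camera adjusted p = 0.00336, adjusted p = 0.546 with an estimated correlation). Atp5a1 (0.73) and Cox5a (0.60) were among those higher. Antimicrobial genes were lower in 10 of 14 cases (10 over the list alone; median -4.57, camera adjusted p = 1.48e-10), and this list alone of the 10 called here held with an estimated correlation (adjusted p = 0.00840). Among them were Pglyrp1, a peptidoglycan-binding protein (304 ± 43.6 against 2863 ± 45.6 CPM), Mptx1 (-7.64) and Defa3 (-7.79). Paneth cells are told apart by such transcripts, so the antimicrobial call follows in part from the class itself.

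Other lists were lower in SEC-PRO than in PANETH with the main scaling and turned positive when library size alone was used. Dissociation and stress response genes were lower in 13 of 16 cases (13 over the list alone; median log2 -1.65, 0.74 with library size alone; camera adjusted p = 1.70e-08, adjusted p = 0.289 with an estimated correlation). Among them were Zfp36 (37.6 ± 18.9 against 216 ± 66.4 CPM), Ier2 (-1.69) and Dusp1 (-2.32). ER to Golgi transport genes were lower in 22 and higher in 2 of 30 cases, the latter Ssr1 (0.65) and Ssr2 (0.81) (22 and 3 over the list alone; median -0.63, 1.77 with library size alone; camera adjusted p = 5.43e-05, adjusted p = 0.384 with an estimated correlation). Those lower included Ssr4 (518 ± 83.8 against 1166 ± 156 CPM), Sec62 (-1.26) and Srp9 (-1.24). Mitochondrial genome transcripts were lower in 12 of 13 (12 over the list alone; median -0.44, 1.96 with library size alone; camera adjusted p = 2.24e-05, adjusted p = 0.374 with an estimated correlation), with mt-Nd3 (-0.62), mt-Nd4l (-0.60) and mt-Nd2 (-0.72). Cell cycle inhibitors went both ways, 8 lower, with Gadd45g (21.9 ± 5.98 against 388 ± 49.5 CPM), Btg2 (-2.20) and Ccng1 (-1.50), and 5 higher, namely Cdkn1b, Cdkn2c, Cdkn2d, Rb1 and Rbl1 (8 and 5 over the list alone; median -0.14, 2.22 with library size alone and 0.16 in replicate 1 alone; camera adjusted p = 0.00900, adjusted p = 0.335 with an estimated correlation). In all, 1926 of 10910 genes were higher in SEC-PRO and 1962 lower (49.5% higher, 98.8% with library size alone). Of these, 99.7% moved the same way in both libraries, which calling from these libraries largely builds in. In thinned cells 1327 genes were called, and 32.0% of the 3888 calls were kept. Library size alone moved the median of all genes from 0.04 to 2.42, with PANETH TMM factors of 0.229 and 0.256, and turned Sox9 (1.11), Olfm4 (0.14) and Ctnnb1 (1.93) positive, so changes are given relative to the TMM zero point.

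Against mature goblet cells, the SEC-PRO class was again set apart by cell division. The replication factor gene Pclaf (ENSMUSG00000040204, chromosome 9, 65890237 to 65903266, plus strand) was at 232 ± 0.744 CPM in SEC-PRO and at 0 in GOBLET. This was at least 20.3-fold higher when the floor of 3 counts over both GOBLET sums was used (edgeR adjusted p = 0.0127). By the same floor, Cenpe, a kinetochore motor, was at least 15.9-fold higher (181 ± 31.6 CPM, edgeR adjusted p = 1.64e-11), and Cdca8, Spc24, Knl1, Cenpa, Ppp1r1b and Npm3 at least 10.0, 9.04, 8.52, 7.88, 7.21 and 6.98-fold higher. GOBLET had 0 counts of each of these genes, so the fitted log2 changes that ranked them are not exact. Then came the 8 largest decreases. Lgals3, a secreted galectin (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160, plus strand), was 118-fold lower in SEC-PRO (7.13 ± 1.86 against 835 ± 148 CPM, log2 -6.88 ± 0.35, edgeR adjusted p = 5.82e-11). Mxd1, an antagonist of Myc (ENSMUSG00000001156, chromosome 6, 86647042 to 86669161, minus strand), was 75.1-fold lower (20.3 ± 6.76 against 1529 ± 18.6 CPM, edgeR adjusted p = 4.84e-09). S100a6, a calcium-binding protein gene, stood at 301 ± 9.96 against 9618 ± 1666 CPM (log2 -4.99 ± 0.30), Fer1l6 at 39.5 ± 3.05 against 713 ± 221 CPM and Ifi27l2b at 121 ± 17.9 against 2073 ± 271 CPM. Between them lay Tm4sf4 (-5.07 ± 0.45), the actin-bundling Espn (-4.63 ± 0.74) and Selenop (-4.18 ± 0.88). Atoh1 was lower in SEC-PRO than in GOBLET (101 ± 13.0 against 207 ± 40.4 CPM, log2 -1.10 ± 0.33, edgeR adjusted p = 0.0185), a call lost under 7 alternatives, among them TMM over all genes (-0.87) and thinned cells (-0.81). Ctnnb1 was lower (149 ± 6.85 against 384 ± 25.7 CPM, log2 -1.38 ± 0.18) and had a value of 0.02 when GOBLET-PRE replaced GOBLET. Sox9 was higher (111 ± 2.21 against 19.2 ± 0.856 CPM, log2 2.54 ± 0.53, 5 GOBLET counts), and Cd44 was at least 1.78-fold higher than in GOBLET, which had 0 counts (edgeR adjusted p = 0.0157, a call lost in thinned cells). Lgr5 (6.07 against 3.09 CPM, 53 and 1 counts, edgeR adjusted p = 0.882), Olfm4 (log2 0.72 ± 1.52, edgeR adjusted p = 0.804) and Apc (-0.46 ± 0.31, edgeR adjusted p = 0.322) did not pass.

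Ribosome and division genes were higher in SEC-PRO than in GOBLET as lists. All 30 measured ribosomal protein genes were higher (30 over the list alone; median log2 1.65, camera adjusted p = 2.35e-31), with Rpl14 at 1432 ± 8.97 against 354 ± 24.8 CPM, Rpl3 at 1.91 and Rpl11 at 1.78. Ribosome biogenesis genes were higher in 20 of 30 cases (22 over the list alone; median 2.69, or 1.81 with 6 genes at their bounds, camera adjusted p = 4.33e-06). Among them were Npm1 at 690 ± 65.9 against 105 ± 8.85 CPM, Ncl at 2.10 and Nop58 at 2.86. With an estimated correlation the adjusted p was 0.187 for both lists. G2/M genes were higher in 29 of 30 cases (30 over the list alone; median 4.77, or 3.44 with 12 at their bounds, camera adjusted p = 3.28e-07, adjusted p = 0.233 with an estimated correlation). Among them were Top2a at 490 ± 17.4 against 25.4 ± 7.90 CPM and Cenpf at 227 against 11.1 CPM. G1/S genes were higher in 25 of 30 (28 over the list alone; median 3.98, or 2.25 with 13 at their bounds, camera adjusted p = 0.00387, adjusted p = 0.370 with an estimated correlation). Mcm4 and Mcm3 were at least 5.24-fold higher and Dut stood at 87.4 against 4.94 CPM. Mitochondrial genome transcripts were higher in 9 of 13 and lower in 1, mt-Co1 (-0.43) (9 and 1 over the list alone; median 0.51, camera adjusted p = 0.00157, adjusted p = 0.417 with an estimated correlation). Those higher included mt-Nd1 (1.16), mt-Nd3 (1.05) and mt-Nd2 (0.92). Oxidative phosphorylation genes were higher in 9 of 30 with 1 lower, Uqcrq (-0.45) (9 and 1 over the list alone; median 0.36, camera adjusted p = 0.0155, adjusted p = 0.592 with an estimated correlation). Those higher included Ndufa4 (1.43), Atp5g1 (1.19) and Atp5a1 (1.22).

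Lower in SEC-PRO than in GOBLET were antimicrobial genes, 12 of 24 against 1 higher, the matrix protease gene Mmp7 (log2 1.84 ± 0.39; 15 and 1 over the list alone; median -1.78, camera adjusted p = 6.24e-04, adjusted p = 0.370 with an estimated correlation). Those lower included Lypd8, which keeps flagellated bacteria from the mucosa, at 955 ± 8.79 against 8467 ± 355 CPM, Pglyrp1 at -1.09 and Sprr2a3 at -5.35. Several of these were Paneth transcripts that free RNA carries, which made up at most 24.4% of UMIs in the GOBLET sum of replicate 1, and Mmp7 itself stood at 960 and 1205 CPM in barcodes with at most 50 UMIs. Fetal-like and injury-response genes were lower in 5 of 11 cases, namely Anxa2, Anxa3, Krt20, S100a6 and Trp53inp1 (5 lower and 1 higher over the list alone; median -0.94, or -1.92 with genes at their bounds, camera adjusted p = 0.00810, adjusted p = 0.370 with an estimated correlation). Anxa2 stood at 211 ± 22.7 against 1439 ± 188 CPM. Brush border genes were lower in 4 of 16 cases, namely Cdhr5 (130 ± 1.62 against 796 ± 63.7 CPM), Vil1 (-1.38), Cdhr2 (-2.30) and Krt20 (-3.96). Their list median of -0.23 (-0.57 with genes at their bounds) turned to 0.34 with library size alone (4 over the list alone; camera adjusted p = 7.65e-04, adjusted p = 0.215 with an estimated correlation). BMP signalling genes were lower in 5 of 12, with Id3, a direct BMP target (55.3 ± 3.61 against 304 ± 45.2 CPM), Bmp2 (-3.65), Smad7 (-2.23), Bmpr1a and Id1. Their median of -0.64 turned to 0.27 with library size alone (6 over the list alone; camera adjusted p = 0.0177, adjusted p = 0.233 with an estimated correlation). Mucin glycosylation genes were lower in 6 of 18 and higher in 1, Slc35a1 (1.46), with Gcnt3 (160 ± 9.73 against 637 ± 148 CPM), Chst4 (-1.99) and Galnt12 (-0.89). Their median of -0.61 (-0.70 with genes at their bounds) turned to 0.30 with library size alone (7 and 1 over the list alone; camera adjusted p = 0.0338, adjusted p = 0.592 with an estimated correlation). In all, 1110 of 10910 genes were higher in SEC-PRO and 1315 lower. Of these, 99.1% moved the same way in both libraries, which calling from these libraries largely builds in. In thinned cells 67.0% of the 2425 calls were kept. The share of higher calls, 45.8%, moved to 58.7% with TMM over all genes, 86.4% with library size alone and 61.7% with GOBLET-PRE in place of GOBLET. The median of all genes moved from 0.11 to 0.33 with TMM over all genes and to 1.02 with library size alone. With count splitting, Rpl3, Rpl11, mt-Nd1, mt-Nd2, mt-Nd3, Ndufa4 and Atp5g1 turned to between -0.19 and -0.01. GOBLET-PRE was the largest class in the biggest of its goblet clusters, but a cluster of 495 cells, also named goblet, was 59.2% ISC. GOBLET sums held 154169 and 232707 UMIs. Simulated changes for this comparison were set in genes with an average log2 CPM above 5. Of these, 50% of log2 changes of 1 and 84% of changes of 2 were recovered.

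The mature Paneth and goblet classes were compared to show how the end points of the secretory branches differ. PANETH had 201 ± 15.7 CPM of Wnt3, a Wnt ligand of the stem cell niche (ENSMUSG00000000125, chromosome 11, 103774150 to 103817957, plus strand), and GOBLET had 0. This was at least 17.6-fold lower by the floor of 3 counts over both sums (edgeR adjusted p = 8.43e-13). Habp2, a secreted serine protease gene (ENSMUSG00000025075, chromosome 19, 56287137 to 56320822, plus strand), was at least 33.3-fold higher in PANETH (380 ± 4.85 CPM). Also higher were the water channel gene Aqp1, Arhgef26, Ndufaf4, Pdcd11, Npm3 and, uncertain because of its overlap with Prap1, Fuom, at least 9.80, 5.97, 4.47, 4.03, 3.84 and 3.83-fold. All of these genes had 0 counts in GOBLET, so the fitted log2 changes that ranked them are not exact. Lower in PANETH were S100a6 (92.9 ± 30.6 against 9618 ± 1666 CPM, 104-fold, edgeR adjusted p = 2.14e-08), Krt20, a keratin of mature surface epithelium (24.5 against 1772 ± 318 CPM, log2 -6.11 ± 0.47), and AW112010 (81.6 against 3356 ± 231 CPM, log2 -5.34 ± 0.20). Others were Lgals3 (-6.04), Ahnak (-6.00), Fer1l6 (-5.65), Clec2h (-5.11) and Mxd1 (-4.62, but 0.37 when GOBLET-PRE replaced GOBLET). Sox9, a factor needed for Paneth cells, was higher in PANETH (271 ± 12.5 against 19.2 ± 0.856 CPM, log2 3.82 ± 0.45, edgeR adjusted p = 1.37e-09). Lgr5 was at 58.2 ± 27.5 against 3.09 ± 4.37 CPM, from 136 and 1 counts (edgeR adjusted p = 0.0234, a call lost under 4 alternatives, among them free RNA subtracted). Atoh1 was lower (99.2 ± 27.6 against 207 ± 40.4 CPM, log2 -1.14 ± 0.35, edgeR adjusted p = 0.0224; lost with DESeq2 size factors at -1.02 and with TMM over all genes at -0.93). Ctnnb1 was lower too (-0.92 ± 0.18, but 0.48 when GOBLET-PRE replaced GOBLET). Olfm4 (2.98 ± 1.19, edgeR adjusted p = 0.115), Cd44 (6.84 against 0 CPM, edgeR adjusted p = 0.227) and Apc (-0.34 ± 0.32, edgeR adjusted p = 0.528) did not pass.

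Of the lists, 8 of 14 antimicrobial genes were higher in PANETH and 2 lower, Lypd8 (1015 against 8467 ± 355 CPM) and Sprr2a3 (9 and 4 over the list alone; median log2 2.61, camera adjusted p = 5.38e-04, adjusted p = 0.158 with an estimated correlation). Pglyrp1 stood at 2863 ± 45.6 against 649 ± 33.5 CPM. Ribosomal protein genes were higher in 30 of 30 cases (30 over the list alone; median 1.22, -0.26 with library size alone; camera adjusted p = 2.23e-25, adjusted p = 0.158 with an estimated correlation). Among them were Rpl12 (1923 against 447 CPM), Rps2 (2.01) and Rpl5 (1.59). Mitochondrial genome transcripts were higher in 12 of 13 (12 over the list alone; median 1.07, -0.41 with library size alone; camera adjusted p = 2.77e-08, adjusted p = 0.225 with an estimated correlation). Among them were mt-Nd3 (1.67), mt-Nd2 (1.64) and mt-Nd1 (1.52). Ribosome biogenesis genes were higher in 19 of 30 (22 over the list alone; median 2.30, or 1.65 with genes at their bounds, camera adjusted p = 1.33e-04, adjusted p = 0.263 with an estimated correlation), with Npm1 (1.65), Ncl (1.25) and Gnl3 (2.76). Dissociation and stress response genes were higher in 11 of 16 (11 over the list alone; median 1.94, camera adjusted p = 2.35e-04, adjusted p = 0.383 with an estimated correlation), with Ier2 (2.04), Zfp36 (2.75) and Btg2 (2.45). Mucin glycosylation genes were lower in 9 of 18 cases (10 over the list alone; median -1.13, camera adjusted p = 9.60e-04, adjusted p = 0.383 with an estimated correlation), with Gcnt3 (-2.01), Chst4 (-4.15) and Galnt12 (-1.48). BMP signalling genes were lower in 8 of 12 and higher in 1, Bmp7 (2.63) (8 and 1 over the list alone; median -1.70, camera adjusted p = 0.00245, adjusted p = 0.158 with an estimated correlation). Those lower included Id3 (18.9 against 304 CPM), Smad7 (-3.26) and Bmp2 (-2.51). Fetal-like genes were lower in 5 of 11, namely Anxa2 (-3.80), Anxa3 (-6.30), Krt7, Krt20 and S100a6, and higher in 2, Cyr61 (3.86) and Trp53inp1 (2.47) (5 and 2 over the list alone; median -1.86, -1.87 with genes at their bounds, camera adjusted p = 0.00307, adjusted p = 0.277 with an estimated correlation). Brush border genes were lower in 3 of 16, Vil1 (-1.23), Cdhr5 (-0.85) and Krt20. The list's median (-0.15, -0.27 with genes at their bounds) and downward test differed in sign from its mean of 1.11, with a median of 0.35 in replicate 2 alone (4 over the list alone; camera adjusted p = 0.0110, adjusted p = 0.277 with an estimated correlation). In all, 925 of 10910 genes were higher in PANETH and 1122 lower. Of these, 99.2% moved the same way in both libraries, which calling from these libraries largely builds in. In thinned cells 1189 genes were called, and 53.4% of the 2047 calls were kept. The share of higher calls, 45.2%, moved to 58.0% with TMM over all genes, 3.099% with library size alone, 66.8% with GOBLET-PRE in place of GOBLET and 59.8% with count splitting. The median of all genes moved from 0.16 to 0.37 with TMM over all genes and to -1.32 with library size alone. With GOBLET-PRE in place of GOBLET, Rps2 (-0.05), Rpl5 (-0.18), Npm1 (-0.01) and Cdhr5 (0.73) changed sign, as did Ncl with library size alone (-0.24).

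**Figure D3:**
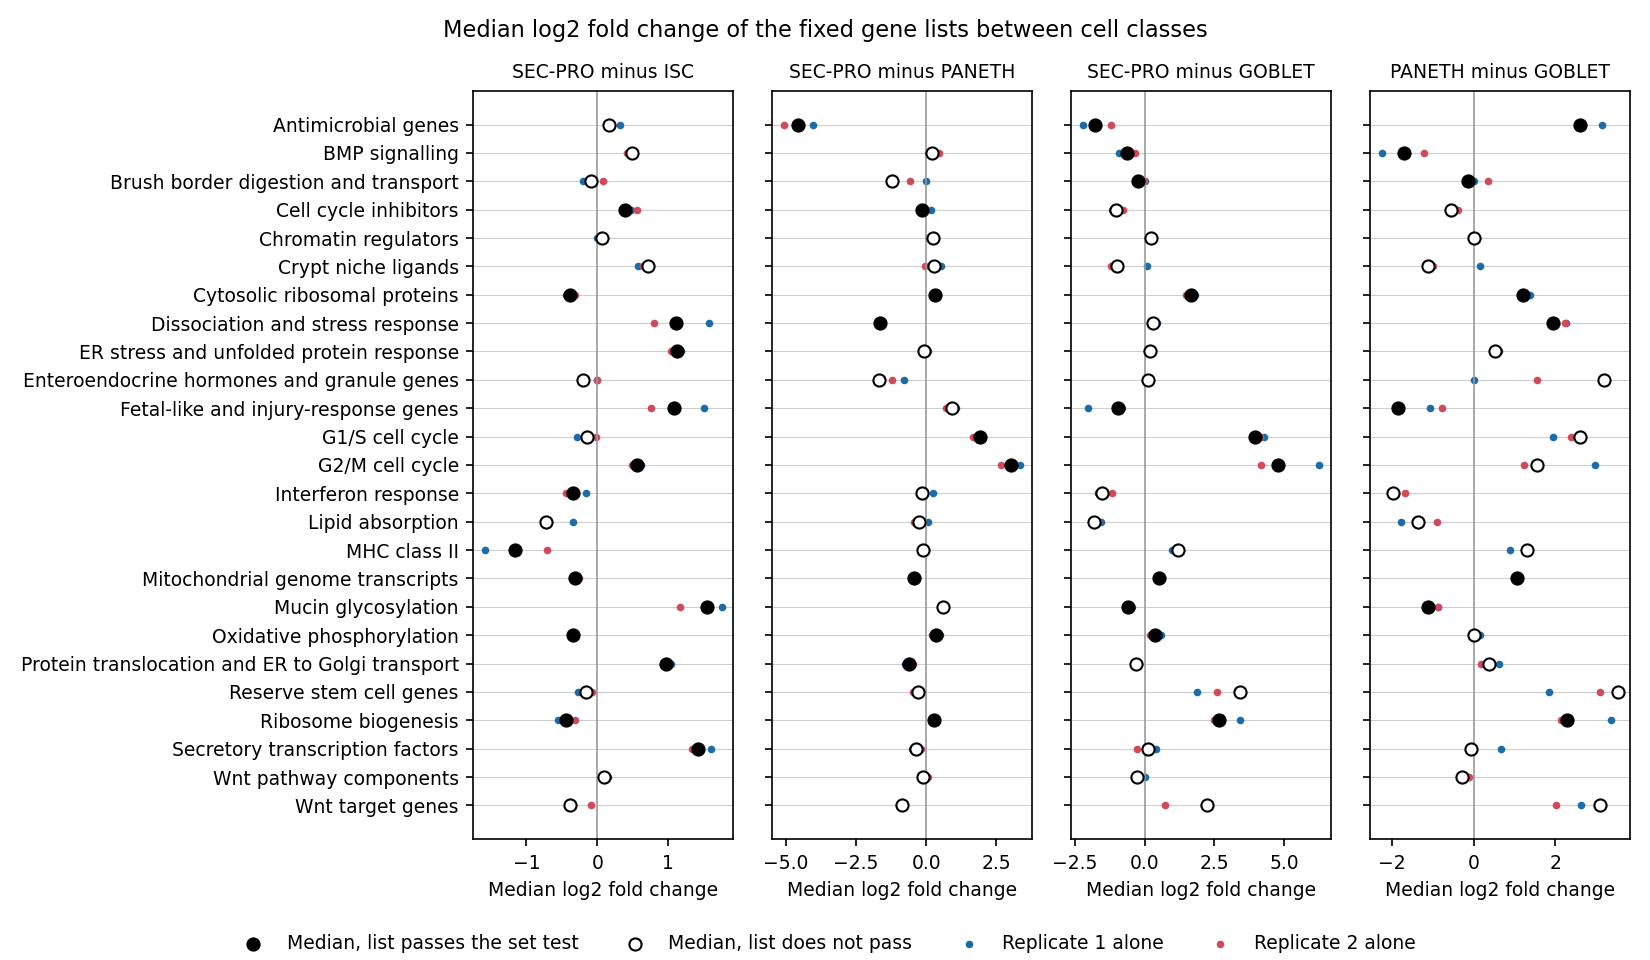
Each panel shows 1 comparison and each line 1 gene list, at its median log2 change (horizontal axis); filled circles passed the set test, open circles did not, and blue and red dots are replicates 1 and 2 alone. G2/M genes lay at 4.77 for SEC-PRO minus GOBLET (3.44 with 12 genes at their bounds), 3.03 minus PANETH and 0.56 minus ISC. Ribosomal protein genes lay at 1.22 for PANETH minus GOBLET, which turned to -0.26 with library size alone.

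Each class was also set against the mean of the other classes, to name genes other than the fixed markers that were higher in it, though not always highest. NON-EC, the hormone cells other than enterochromaffin cells, were led by the incretin gene Gip (1790.3 ± 1635 CPM against a mean of at most 4.33 in any other class, edgeR adjusted p = 1.11e-76), the ghrelin gene Ghrl (2738 ± 235 against at most 14.3 CPM) and Pyy (1666 ± 903 against at most 9.11 CPM). No exact fold is given for them, since Gip had 0 counts in GOBLET, EEC-PRE and EC, Ghrl in EC and Pyy in GOBLET. The log2 values of other genes in these contrasts are likewise fitted, and not exact where a class had 0 counts, as GOBLET had for Habp2. Gip differed between the libraries (634 and 2946 CPM). EC, the serotonin-making enterochromaffin cells, were led by the serotonin synthesis gene Ddc (848 ± 280 CPM, log2 5.67 ± 0.23), which stood at 505 ± 65.3 CPM in NON-EC. TUFT was led by Lrmp (ENSMUSG00000030263, chromosome 6, 145115653 to 145174934, plus strand), at 933 ± 253 CPM against at most 9.89 in any other class (log2 8.63 ± 0.13). PANETH-PRE was led by Samd5 (log2 5.79 ± 0.15) and Habp2 (5.71 ± 0.17), both of which were higher still in PANETH (257 ± 4.61 against 490 CPM and 198 ± 17.8 against 380 CPM). It exceeded PANETH in the ribonuclease gene Rnase1 (816 ± 66.4 against 128 CPM). GOBLET-PRE was led by the EGF receptor ligand gene Areg (81.4 ± 16.3 CPM, log2 3.01 ± 0.22). ENTERO-PRO was led by Spink1 (640 ± 256 CPM, log2 6.27 ± 0.20) and the lipoprotein gene Apob (758 ± 288 CPM, log2 5.22 ± 0.23), and GP was led by Ccl9 (2.11 ± 0.23; 260 ± 78.3 CPM against 822 in PANETH-PRE), with Spdef at 207 ± 13.6 CPM (1.85 ± 0.10). SEC-PRO and ISC were led by division genes such as Knl1 (4.34 ± 0.18 and 3.80 ± 0.19) and Pclaf (4.16 ± 0.30 and 4.11 ± 0.30). Counts of genes higher and lower were 3066 and 2679 for ISC, 2048 and 1128 for SEC-PRO, 1166 and 1306 for GP, 1764 and 2201 for GOBLET-PRE, 1285 and 728 for GOBLET, 1444 and 1044 for PANETH-PRE, and 1935 and 1166 for PANETH. For EEC-PRE they were 1337 and 682, for EC 1749 and 521, for NON-EC 2431 and 600, for TUFT 1383 and 851, and for ENTERO-PRO 1657 and 1244. With TMM over all genes the share of higher genes moved from 53.4% to 65.4% in ISC, 47.2% to 73.4% in GP, 44.5% to 70.1% in GOBLET-PRE, 63.8% to 51.6% in GOBLET, 58.0% to 69.4% in PANETH-PRE, 77.0% to 54.6% in EC, 80.2% to 62.3% in NON-EC and 57.1% to 73.6% in ENTERO-PRO. With library size alone it fell to 26.5% in GOBLET, 26.9% in PANETH-PRE and 1.37% in PANETH, and rose in the other 9 classes, to between 65.4% in GOBLET-PRE and 96.4% in NON-EC. With DESeq2 size factors it moved to 64.9% in ISC, 59.6% in GP, 55.8% in GOBLET-PRE, 65.1% in EC and 65.4% in NON-EC.

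The libraries of a class differed least in GOBLET-PRE and most in GOBLET. Across 3827 genes of an average log2 CPM of at least 5, which are not independent replicates, Pearson's r between the libraries of a class ran from 0.822 in GOBLET to 0.982 in GOBLET-PRE. In CPM without TMM factors, the share of those genes that differed by more than 1 log2 unit was 0.915% in GOBLET-PRE, 1.02% in SEC-PRO, 2.14% in ISC and 21.1% in GOBLET. With TMM factors it was 0.915%, 1.07%, 1.75% and 21.9%.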

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

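The tests of Mmp7, of Lgr5, of class assignment and of the gene and mitochondrial limits given here were chosen after the result was seen, though for these limits the bounds were written before the ratios they judge were computed.

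Signals appeared in barcodes that the comparisons between classes did not use. In barcodes with at most 50 UMIs, the stromal gene Dcn averaged 418 CPM (490 and 346 CPM in replicates 1 and 2), against 0.0670 CPM in listed cells. The immune gene Gzma averaged 21.6 CPM there (14.9 and 28.3 CPM), above the 2.48 and 2.57 CPM that a count of 0 allows, and 0.335 CPM in listed cells. Of barcodes with 3000 or more genes that the authors' table does not list, 38.1% in replicate 1 (363 of 953) and 67.5% in replicate 2 (131 of 194) lay nearest to the ISC profile.

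The ISC share was 2.67 times as high in replicate 2 as in replicate 1 (95% interval 2.44 to 2.91). Assignment of cells to classes is argued against as its cause, since clusters computed anew gave a ratio of 2.47 (2.28 to 2.68). The limits on genes and on mitochondrial UMIs stay open, because adding back the barcodes with 3000 or more genes gave 1.98 (1.84 to 2.13) and adding back those with at least 7% mitochondrial UMIs gave 1.66 (1.56 to 1.75), both between the bounds of 2 and 1.5. The limits may thus account for part of the difference, as both together gave 1.53 (1.45 to 1.61). However, barcodes were placed by their nearest profile, which put 75.5% of listed cells, and 89.0% of ISC, in the authors' class. The returned barcodes lie outside the limits of the listed cells, so these rates may not hold for them. The design has 1 group, so no biological explanation was tested.

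Mmp7, a protease that activates Paneth defensins, was detected well outside the Paneth classes, at 966 ± 139 CPM in SEC-PRO, 1054 ± 247 in GP and 1109 ± 56.6 in GOBLET-PRE, against 216 ± 106 in ISC and 10895 ± 869 in PANETH. Free RNA is argued against as the sole source, because the ratio of Mmp7 to Defa24 in the sums was at least 7.57 times that in barcodes with few UMIs, and 1 source keeps its genes in 1 ratio. The bound set for Defa24 did not decide on doublets with Paneth-lineage cells. Free RNA was subtracted from Mmp7 but not from Defa24, which can only raise the values that follow. Of the level that PANETH-PRE RNA would have brought with this much Mmp7, Defa24 reached 0.199 and 0.346 in SEC-PRO, 0.217 and 0.416 in GP, and 0.278 and 0.555 in GOBLET-PRE. All 6 values lay under 1 and 5 under the bound of 0.5, which had to hold in every sum. The bound of 0.5 was at first replaced, once the value of 0.555 was known, by a looser one that ruled doublets out, and was then restored. PANETH-PRE held 6983 CPM of Mmp7, 21443 of Lyz1 and 198 of Habp2. In SEC-PRO, GP and GOBLET-PRE, Lyz1 averaged only 593, 647 and 667 CPM (406 in ISC) and Habp2 4.50, 4.66 and 4.26. Both fell far short of Mmp7, which argues against doublets as its sole source. However, no bound was set for either gene, and the bound set for Defa24 did not decide. Wnt3 in SEC-PRO (19.9 against 137 CPM in PANETH-PRE) did not fall short. The design has 1 group, so no biological explanation was tested.

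Lgr5 stood at 43.4 and 50.2 unscaled CPM in PANETH-PRE, beside 73.8 and 46.5 in ISC, whereas Ascl2, another stem cell transcript, stood at 2.35 and 2.51 against 43.1 and 26.6. Free RNA alone is argued against, since the lower 95% bound of Lgr5 in PANETH-PRE was at least 1.72 times its level in barcodes with few UMIs. Doublets with ISC are argued against, since Olfm4 reached at most 0.140 of the level that ISC RNA would have brought with this much Lgr5. PANETH-PRE may therefore hold Lgr5 transcripts of its own, a hypothesis found on these data. PANETH stood at 58.2 ± 27.5 scaled CPM beside 54.5 ± 4.56 in PANETH-PRE, so the signal is not shown to be particular to the precursors. Neither test was run in PANETH. Free RNA made up at most 2.63% and 7.43% of UMIs there, which argues against it as the sole source. Nearest-profile placement returned only 48.3% of PANETH-PRE cells to that class. No biological explanation was tested, since the design has 1 group.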

How the results depend on the processing

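GOBLET-PRE in place of GOBLET, no factors, TMM over all genes, removal of the top 5% of doublet scores and the barcodes added back were tests chosen after the result was seen, and the others were planned. Under alternatives with a test, direction and side of the threshold held for 3217 of 3377 values of named genes (114 weaker, 11 stronger, 35 reversed) and for 286 of 456 list values (169 weaker, 1 stronger). The gene total includes removal of Scrublet's 4 calls, which could change little, and 278 of 278 values held there. Of list values, 227 of 228 held with markers kept in, but only 59 of 228 with an estimated correlation. With 1 library left there was no test, and only the sign could change. It held for 454 of 456 list values. No count is given for named genes, since those chosen by fold had to have the same direction in both libraries. Of counts of called genes 165 of 193 stayed within 1.5 times the main count, and of composition values 68 of 79, but of transcript shares only 45 of 168, moved by less than 1 SD. A share without 1 library always lies within 1 SD of the mean of 2. The 12 composition values for each library left out are thus counted as held and say nothing of stability. Count splitting gave single-class contrasts only for the 7 classes its clusters could name. Where no cause is given below, the cause was not tested.

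With no factors, genes called were 4079 for SEC-PRO against GOBLET, 10019 against PANETH, 4001 for PANETH against GOBLET, and 5484 for SEC-PRO, 3908 for GP, 8264 for PANETH, 4811 for NON-EC and 4106 for TUFT against the other classes. GOBLET-PRE in place of GOBLET gave 4598 (SEC-PRO) and 3682 (PANETH), which changed both the class compared and the depth of its sums. Without the library term the counts were 1886 for SEC-PRO against ISC, and 1877 for SEC-PRO, 1254 for GP and 2641 for GOBLET-PRE against the others. Of the genes called for SEC-PRO against ISC, 50.3% kept their call without that term. In thinned cells, which hold fewer UMIs by construction, counts were 1327 for SEC-PRO against PANETH, 2413 against ISC and 1189 for PANETH against GOBLET, and against the other classes 1985 for SEC-PRO, 1524 for GP, 2635 for GOBLET-PRE, 1317 for PANETH-PRE, 980 for PANETH, 1293 for EEC-PRE, 1332 for EC, 1856 for NON-EC, 1378 for TUFT and 1567 for ENTERO-PRO, or 21211 for each class against the mean of the other classes added up. Lists called in the 4 pairwise comparisons came to 1 with an estimated correlation.

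With barcodes added back, ISC held 21.7% and 33.2% of cells in replicates 1 and 2, from 10.4% and 27.8%. GOBLET-PRE held 31.1% and 19.8%, from 43.7% and 23.4%. Mean shares were then SEC-PRO 15.1%, GP 12.7%, PANETH-PRE 3.92%, EEC-PRE 1.05%, NON-EC 1.41% and ENTERO-PRO 3.74%. In cells with at least 2000 UMIs they were GP 12.1%, EEC-PRE 0.977% and NON-EC 1.68%, and in own clusters secretory progenitors, with SEC-PRO as the largest class of each cluster, were 12.6% and enterocytes 2.03%. Shares of cells with a transcript, first unthinned and then thinned with at least 2 UMIs, were 19.2% and 2.55% for Lgr5 in ISC, 71.8% and 52.0% for Olfm4 in ISC, 58.7% and 19.7% for Mki67 in ISC, 38.5% and 3.23% for Atoh1 in SEC-PRO, 32.2% and 2.50% for Dll1 in SEC-PRO, 33.3% and 1.69% for Apc in SEC-PRO, and 83.1% and 56.0% for Neurog3 in EEC-PRE. These follow from depth and the higher minimum.

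Values that changed sign are log2. For SEC-PRO against GOBLET, count splitting gave Rpl11 -0.077, Rpl3 -0.063, mt-Nd1 -0.014, mt-Nd3 -0.047, mt-Nd2 -0.015, Ndufa4 -0.051 and Atp5g1 -0.19. GOBLET-PRE in place of GOBLET gave Atp5g1 -0.075 and Ctnnb1 0.019, and no factors gave Galnt12 0.016. For SEC-PRO against PANETH, no factors gave Ccng1 0.89, Btg2 0.20, Ier2 0.70, Dusp1 0.060, mt-Nd3 1.78, mt-Nd4l 1.80, mt-Nd2 1.67, Ndufa1 1.71, Ssr4 1.22, Sec62 1.14, Srp9 1.17, Olfm4 0.14, Ctnnb1 1.93, Sox9 1.11 and Apc 2.28. For PANETH against GOBLET, GOBLET-PRE in place of GOBLET gave Mxd1 0.37, Cdhr5 0.73, Rps2 -0.049, Rpl5 -0.18, Npm1 -0.011 and Ctnnb1 0.48. Count splitting gave Cdhr5 0.65, Rps2 -0.094 and Ctnnb1 0.36, and no factors Ncl -0.24. List medians also changed sign. Cell cycle inhibitors, SEC-PRO against PANETH, gave -0.22 without replicate 1 and 0.16 without replicate 2. Brush border digestion and transport, PANETH against GOBLET, gave 0.35 without replicate 1 and 0 without replicate 2.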

Other observations

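The tests in this part are those planned for lists and named genes. The lists described were picked from all lists after their values were seen.

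MHC class II genes were higher in ISC, ENTERO-PRO and PANETH-PRE. All 7 measured genes were higher in ISC than in the mean of the other classes (7 over the list alone; median log2 1.44, camera adjusted p = 0.00568, adjusted p = 0.268 with an estimated correlation), as were 6 of 7 in ENTERO-PRO (6 over the list alone; median 1.43, camera adjusted p = 9.21e-04, adjusted p = 0.344 with an estimated correlation) and 6 of 7 in PANETH-PRE (6 over the list alone; median 1.22, camera adjusted p = 0.00343, adjusted p = 0.329 with an estimated correlation). Cd74, the invariant chain of MHC class II, stood at 1148 ± 263 CPM in ISC, 1256 ± 286 in ENTERO-PRO and 991 ± 123 in PANETH-PRE. Oxidative phosphorylation genes were higher in 29 of 30 cases in ENTERO-PRO (30 over the list alone; median 0.78, camera adjusted p = 7.32e-18, adjusted p = 0.0958 with an estimated correlation). In ISC 29 were higher as well and 1 lower, Ndufa1 (29 and 1 over the list alone; median 0.53, camera adjusted p = 9.43e-09, adjusted p = 0.242 with an estimated correlation), and these classes were not compared. Genes of the secretory machinery were lower in TUFT than in the mean of the other classes, with 21 of 24 ER stress genes lower (24 over the list alone; median -0.92, camera adjusted p = 1.93e-10, adjusted p = 0.216 with an estimated correlation) and 27 of 30 ER to Golgi transport genes, with Sec11c the 1 that was higher (27 and 1 over the list alone; median -0.76, camera adjusted p = 1.82e-12, adjusted p = 0.216 with an estimated correlation). This was not particular to TUFT, since in ISC the medians of these lists were -0.89 (23 of 24 lower, 23 over the list alone, camera adjusted p = 1.13e-06) and -0.77 (29 of 30 lower, 29 over the list alone, camera adjusted p = 5.59e-08). In EEC-PRE they were -0.86 (15 of 24 lower, 20 over the list alone, camera adjusted p = 5.97e-07) and -0.69 (21 of 30 lower, 24 over the list alone, camera adjusted p = 1.47e-07). With an estimated correlation the adjusted p was 0.242 for both lists in ISC, and 0.273 and 0.267 in EEC-PRE. These medians kept their sign under each scaling that was run.

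Chromatin regulators were mostly lower in GOBLET-PRE than in the mean of the other classes. There 20 of 24 were lower, among them Ezh2 and Tet2, and 1 was higher, the homeobox gene Cdx1 (20 and 1 over the list alone; median -0.55, camera adjusted p = 2.41e-04, adjusted p = 0.137 with an estimated correlation). In NON-EC 14 of 24 were higher, among them Kdm6b, Dnmt3a and Tet3 (14 over the list alone; median 0.57, camera adjusted p = 0.00350, adjusted p = 0.261 with an estimated correlation), with no change of sign under each scaling that was run. In EEC-PRE 11 were higher and 2 lower (13 and 2 over the list alone; median 0.68, camera adjusted p = 0.00716, adjusted p = 0.267 with an estimated correlation), and in EC 9 were higher and 1 lower (15 and 1 over the list alone; median 0.64, camera adjusted p = 0.0305, adjusted p = 0.356 with an estimated correlation). In GP 11 were lower and 1 higher (14 and 1 over the list alone; camera adjusted p = 0.00176, adjusted p = 0.186 with an estimated correlation), with a median of -0.32 that turned to 0.055 with library size alone. In TUFT 8 of 24 were higher (12 over the list alone; median 0.37, camera adjusted p = 0.00661, adjusted p = 0.222 with an estimated correlation), and in GOBLET the list did not pass (camera adjusted p = 0.339). The differences between these contrasts were not tested. NON-EC had higher levels of all 11 measured hormone and granule genes (11 over the list alone; camera adjusted p = 2.27e-10), a call that held with an estimated correlation (adjusted p = 0.00299). Its fitted median of 9.11 is not exact, since genes such as Gip had 0 counts in some classes. Hormone cells are told apart by such transcripts, so the call follows in part from the class itself. Wnt3 was found beyond the Paneth lineage in all 3 hormone classes, at 81.6 ± 0.844 CPM in EEC-PRE, 51.7 ± 0.351 in NON-EC and 44.6 ± 5.68 in EC, against 201 ± 15.7 in PANETH, 137 ± 9.06 in PANETH-PRE, 19.9 ± 0.324 in SEC-PRO and 4.23 ± 1.66 in ISC.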
